A study of Mus musculus with 7 samples.

How the data were processed

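Polyadenylation selection, strandedness and read length are not given in the sources used here; the labels' protocols say that total RNA was extracted with Trizol and that libraries were made by a standard Illumina method. Per the submitters' processing notes, TopHat2 2.0.13 and Cuffdiff 2.2.0 were used, with no settings or genome build named. The authors deposited a table for each of 7 comparisons of 2 libraries, with FPKM (fragments per kilobase of transcript, scaled to mapped fragments) of 23996 genes in both, and the Cuffdiff p-value and q-value of the pair, per the file headers. The p-values and q-values in the authors' deposited tables compare 2 libraries without replicates, and they are quoted only as the authors' values. FPKM of a library were the same in each table that holds it (largest difference 1.1e-16), so the 7 libraries were joined into 1 matrix. Smaller sheets were checked against the full tables: they hold genes that Cuffdiff marked as testable with an FPKM above 0 in both libraries and at least 2-fold different, then those with p under 0.05, then those with q under 0.1. A line of each full table was empty (1 line per table), and that gene is not reported here. Which libraries a table holds was taken from its sample name cells, because the sample to which a table is attached was often not in it. Loci in the tables overlapped the gene of the same symbol in GENCODE release M21 for 22352 of 22580 symbols (99.0%). Genes listed at 0 are given per library, with no fold, since a 0 can be a failed estimate.

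The conditions are 0h control, 4h MDI, 4h CM, 24h MDI, 24h CM, Pro MDI and Pro CM, with 1 library each. Because no condition was replicated, comparisons of 2 libraries used a rule of size and no test: a difference of at least 1 in log2(FPKM + 1), over genes with an FPKM of at least 1 in at least 1 of the 2 libraries. Gene lists (26, holding 446 different genes of which 437 are in the tables) were described by the median difference of measured members and its percentile among 10000 random lists of the same size matched on mean expression in 10 bins. Lists with under 3 measured members, those of other cell types in most comparisons, have no median. Model tests used limma 3.58.1 with an intensity trend on log2(FPKM + 1) and Benjamini-Hochberg adjustment at 0.05. The medium effect was fitted to the 6 treated libraries with stage as a block, and time contrasts to all 7 libraries with stage and medium as terms; both leave 2 residual degrees of freedom, which hold the stage-by-medium interaction and library noise, so the p-values do not measure the spread of cultures. Some small RNA genes are at 0 in every treated library, and their very small standard errors are unreliable. Camera used a preset correlation of 0.01 and, again, an estimated correlation.

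The designs, the lists, the main alternatives and the rule for named genes were fixed before the data were examined. The rule took, for each pair, the 6 highest and 6 lowest genes with an FPKM of at least 5, up to 4 members of each list, 12 fixed genes and the up to 10 genes with the largest difference in the authors' list at q under 0.1. For each limma contrast it took the 10 smallest adjusted p per direction, for the medium effect among genes that differed the same way at the 3 stages. As nearly all of the highest and lowest genes were small RNA genes, the 8 highest and 8 lowest protein-coding genes were added after the values were seen. Alternatives were a pseudocount of 0.1 or 5, no low-value filter, an FPKM of at least 5, rescaling to a median ratio of 1 or to TPM, limma without trend, a threshold of 0.1, and fits without a pair of libraries. Depth per library is unknown, so no counting intervals are given. FPKM sums ran from 558532 in the 0h control to 714427 in 4h MDI. In simulated data for the medium effect, limma recovered 72% of 2-fold changes and 100% of 4-fold changes over 11463 genes with 10 false calls. For 4h against 0h it recovered 10% and 92%, with 11 false calls over 11724 genes. The simulated noise was normal, independent between genes, drawn from limma's shrunken spread and without a stage-by-medium interaction. Recovery in the real data may therefore be lower. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.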

Results

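RNA-seq was made from mouse 3T3-L1 cells, an embryonic fibroblast line that turns into fat cells when given hormonal inducers, with 7 libraries in 7 conditions. The 0h control was taken from confluent cells before differentiation. Libraries at 4 h and 24 h came from cells given MDI, a mixture of IBMX (which raises cAMP by blocking phosphodiesterases), dexamethasone (a synthetic glucocorticoid) and insulin, or conditioned medium (CM), which was MDI medium taken from 3T3-L1 cells that had been differentiating for 48 h. A further pair, labelled Pro MDI and Pro CM, came from preconfluent cells, with no time given. The stated purpose was to look for a factor that matters for 3T3-L1 differentiation. The values are FPKM for 23996 genes. No condition was replicated, so a difference between 2 libraries has no replicate check, and it is given here with both values. Between 10530 and 11101 genes had an FPKM of at least 1 in a library. Depth is unknown, because FPKM carry no read totals. The spacing of low values placed the worth of a read in the libraries within 1.4-fold of each other. That estimate was searched only in a narrow window around the 0h library, so a wider range was not excluded. Its peak was weakest in 4h MDI, at 1.82 times the median density. Differences are on the log2(FPKM + 1) scale, which understates changes of weakly expressed genes. Loci are those the authors give, with 1 added to each start.

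The first question was what changed within 4 h of giving the inducers. There was no library without inducers at 4 h or 24 h. In every comparison with 0h the inducers, the new medium and elapsed time therefore cannot be told apart. Most targets of the glucocorticoid receptor, and many of the cAMP and CREB targets, rose. Fkbp5, a co-chaperone of the receptor, had an FPKM of 44.2 at 0h, 390 in 4h MDI and 477 in 4h CM. The metallothionein Mt2 (chromosome 8, 94172618 to 94173567) went from 186 at 0h to 7475 in MDI and 4318 in CM. The median of the glucocorticoid list was 2.14 higher in 4h MDI and 2.69 higher in 4h CM than at 0h. In limma, with both media and all 7 libraries in the fit, 12 of its 17 measured members rose and none fell (14 rose and 1 fell when adjusted over the list alone). Targets of cAMP and CREB had medians of 2.14 in MDI and 1.95 in CM. Of 17 members 9 rose, among them the orphan receptor Nr4a1 (10.3 at 0h, 434 in MDI, 271 in CM) and the phosphodiesterase Pde4b (6.19, 39.7 and 33.1), and 2 fell (10 and 2 when adjusted over the list alone). Of 15 immediate early genes 5 rose and none fell, over all genes tested and when adjusted over the list alone. They included the growth regulator Myc, whose log2 change was 4.54 (SE 0.30, adjusted p = 0.0243), and the AP-1 subunit Fosl1, at 2.64 at 0h, 240 in MDI and 144 in CM. Glycolytic and hypoxia-linked genes had medians of 1.57 and 1.15. Of 16 members 3 rose over all genes and 9 when adjusted over the list alone, and none fell. Hk2, the first enzyme of glycolysis, was at 4.49 at 0h, 110 in MDI and 48.9 in CM.

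Interferon-stimulated genes, which encode antiviral proteins, moved the other way. In limma 12 of 18 measured members fell at 4h and none rose (15 when adjusted over the list alone). Isg15 was at 49.1 at 0h, 29.2 in 4h MDI and 14.6 in 4h CM, and Oasl2 at 29.3, 5.34 and 3.16. Among the adipogenic regulators, Cebpb, an early inducer of the fat cell program, had an FPKM of 124 at 0h, 695 in MDI and 784 in CM, and Cebpd 6.23, 30.8 and 45.8. Both rose in limma (adjusted p = 0.025 and 0.0395). Klf5 rose as well, from 11.3 to 93.9 and 98.8. Over the whole list 3 of 18 rose and 2 fell (5 and 3 when adjusted over the list alone). Mature adipocyte genes gave 1 rise and 1 fall among 14, over all genes and over the list alone. None of 20 mitotic genes passed the test at 4h, over all genes or over the list alone, and of 25 DNA replication genes 1 rose and 2 fell (1 and 0 when adjusted over the list alone). Ccnb1, the cyclin that drives entry into mitosis, was at 6.56 at 0h, 5.83 in MDI and 5.89 in CM. Clock genes included 4 that rose and 3 that fell among 14 (4 and 5 when adjusted over the list alone). Per2 was at 1.53 at 0h, 23.8 in MDI and 22.4 in CM, and rose, and Dbp was at 13.4, 0.524 and 1.34 and fell. Fatty acid synthesis genes split, with 3 of 13 up, Fasn among them (27.6, 102 and 84.9), and 1 down (4 and 3 when adjusted over the list alone).

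Over all 11724 genes tested, 1902 changed between 0h and 4h in limma at a Benjamini-Hochberg adjusted p under 0.05, 965 upwards and 937 downwards. Vdr, the vitamin D receptor gene, was among the smallest adjusted p (log2 change 5.56, SE 0.32, adjusted p = 0.0237; 6.95 at 0h, 387 in MDI, 362 in CM), as were Pmvk, a mevalonate pathway kinase (4.46, SE 0.17, adjusted p = 0.00615), and Arl4d (4.91, SE 0.21, adjusted p = 0.00772). Serpinb8, a serine protease inhibitor, fell by 3.27 on the log2 scale (SE 0.17, adjusted p = 0.0188). Compared as single pairs, 1531 genes were at least 2-fold higher and 1599 at least 2-fold lower in 4h MDI than at 0h, and 1075 higher and 1054 lower in 4h CM. The authors' deposited table held 35 genes at least 2-fold different, with an FPKM above 0 in both libraries and q under 0.1, for 4h MDI, and 23 for 4h CM. The balance of directions depended on the scaling and on the pseudocount. Rescaling to TPM shifted the ratio of each gene, before the pseudocount, by -0.36 in 4h MDI and -0.29 in 4h CM on the log2 scale. TPM were also larger than FPKM here, so the same pseudocount and filter weighed less on weakly expressed genes. The TPM counts mix these effects. With median-of-ratios scaling limma called 777 upwards and 1531 downwards, and after rescaling to TPM the split was 1035 higher and 2990 lower in 4h MDI, and 739 and 2048 in 4h CM. A pseudocount of 5 turned the pair counts the other way, with 1069 higher and 582 lower in 4h MDI, and 706 and 365 in 4h CM, but gave 969 upwards and 1229 downwards in limma. The limma residual came from the interaction of stage and medium and from library noise, not from replicate cultures, and the 0h library was assumed to vary like the others; without the low-value filter 1185 genes passed, and at a threshold of 0.1 4051 did.

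By 24h genes of cell division were raised. Each of the 20 mitotic genes rose against 0h in limma, over all genes and over the list alone, with list medians of 3.06 in 24h MDI and 2.56 in 24h CM. Ccnb1 was at 77.2 in MDI and 50.4 in CM, and Top2a, a DNA topoisomerase of dividing cells, went from 9.69 at 0h to 130 and 149 (log2 change 3.72, SE 0.23, adjusted p = 0.0154). DNA replication genes followed, with 14 of 25 rising and none falling (22 when adjusted over the list alone). The helicase subunit Mcm5 was at 5.47 at 0h, 34.5 in MDI and 19.8 in CM. Of 5 measured histone genes 2 rose (4 when adjusted over the list alone), with H2afx at 34.1, 191 and 143. The respiratory chain list had 3 of 22 members up and none down (5 when adjusted over the list alone).

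Some matrix and contractile genes fell over the same interval. Of 26 extracellular matrix genes 9 fell and none rose (13 fell and 4 rose when adjusted over the list alone), including the collagen gene Col1a1 (1996 at 0h, 425 in MDI, 614 in CM) and Thbs2 (241, 7.30 and 12.8). Of 12 actin and SRF or YAP target genes 5 fell and none rose, over all genes and over the list alone. Acta2, smooth muscle actin, was at 82.9, 7.67 and 3.56. All 18 measured interferon-stimulated genes fell, over all genes and over the list alone, with Oasl2 at 1.01 in MDI and 0.508 in CM. Of the glucocorticoid targets 5 of 17 rose and none fell (10 and none when adjusted over the list alone). Of the preadipocyte genes 1 of 15 rose (Ly6a) and 1 fell (Pdgfrb), against 1 and 4 over the list alone. Dlk1, an inhibitor of fat cell formation, was at 669 at 0h, 551 in MDI and 307 in CM, and its change did not pass. No mature adipocyte gene among 14 passed in either direction. The list median against 0h was 1.87 in 24h CM, over 14 measured members, and 0.39 in 24h MDI, over 12. Lcn2, which encodes a secreted lipid carrier, had the largest difference of all protein-coding genes in both media, at 0.0408 at 0h, 219 in MDI and 275 in CM. The keratin gene Krt13 rose by 5.42 on the log2 scale (SE 0.32, adjusted p = 0.0154), while the esterase gene Ces1a fell by 4.29 (SE 0.19, adjusted p = 0.00815) and Islr fell by 4.99 (SE 0.25, adjusted p = 0.0131).

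In total 1365 of 11724 genes changed between 0h and 24h in limma, 618 upwards and 747 downwards. As single pairs, 1017 genes were at least 2-fold higher and 1259 lower in 24h MDI, and 937 and 1139 in 24h CM. After rescaling to TPM, which shifted the ratios before the pseudocount by -0.31 and -0.19, the counts were 748 and 2189, and 784 and 1722. Among genes at least 2-fold different with an FPKM above 0 in both libraries, the authors' deposited table had 9 at q under 0.1 for 24h MDI. It had 6 such genes for 24h CM, with the receptor gene Pdgfrb, Thbs2, Top2a and Glul in both. Without these limits, Cuffdiff marked 16 genes as significant for 24h MDI and 24 for 24h CM. Without the 4h libraries, a fit chosen after the data were seen, 793 genes passed, and at a threshold of 0.1 2695 did. At 24h against 0h the preset-correlation camera test called the mitotic (adjusted p = 3.99e-15), interferon (adjusted p = 6.97e-14) and glucocorticoid lists (adjusted p = 0.000264). It also called others, such as DNA replication (adjusted p = 1.35e-10) and extracellular matrix genes (adjusted p = 0.000264). No list of any time contrast or of the medium contrast was called with an estimated correlation. The mitotic, interferon and glucocorticoid lists had adjusted p = 0.472, 0.443 and 0.443 in that version of camera. With 2 residual degrees of freedom it could hardly call any list.

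**Figure D1:**
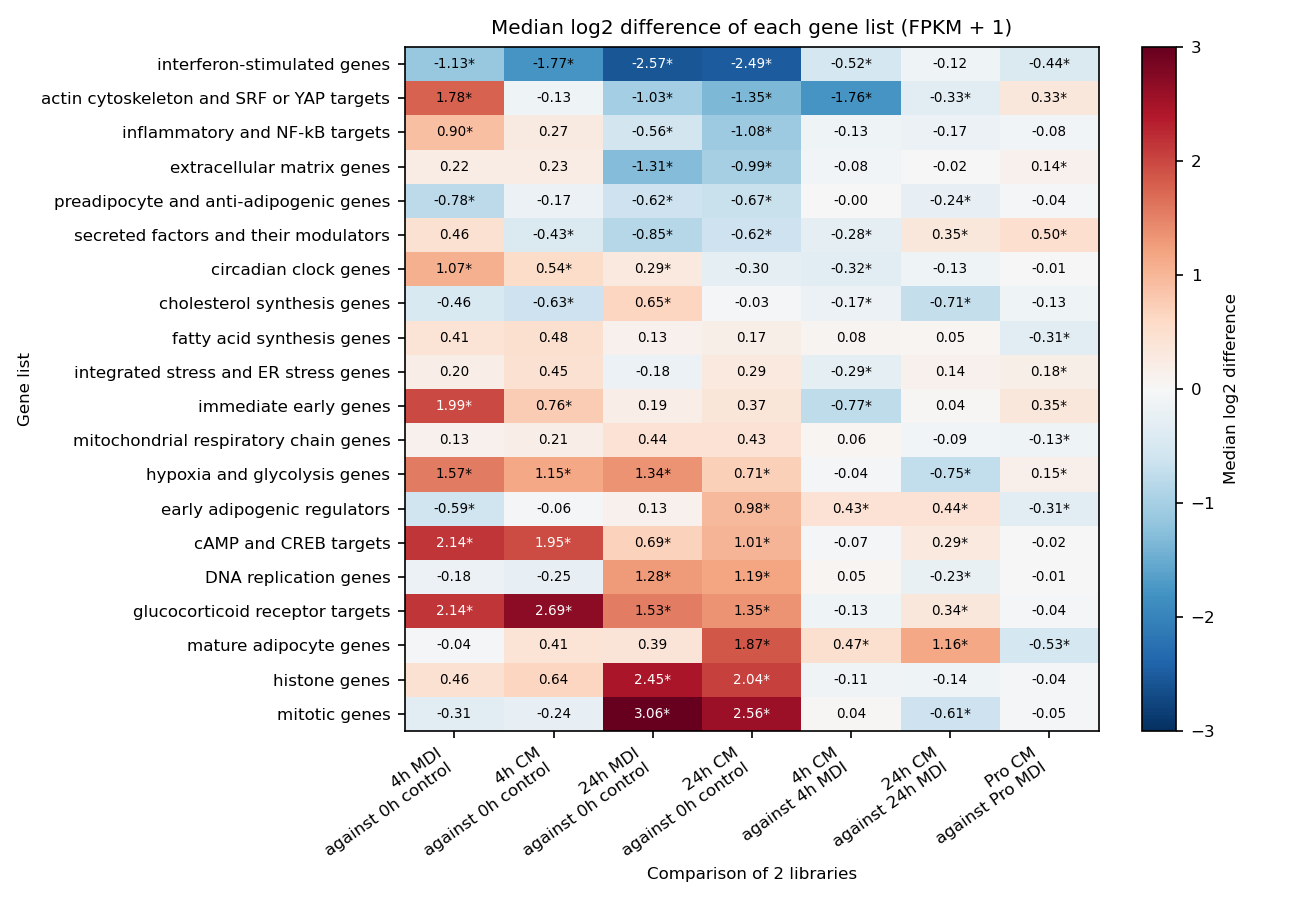
Median log2(FPKM + 1) difference of each gene list (rows) in each comparison of 2 libraries (columns), coloured from blue (lower) to red (higher), with a star where the median lay outside the middle 95 percent of 10000 random lists matched on expression. Mitotic genes reached 3.06 in 24h MDI, interferon-stimulated genes were at -2.57 there, and the actin list was -1.76 for CM at 4h and 0.33 in the Pro pair.

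Between 4h and 24h, mitotic and most DNA replication genes rose, while part of the early response lists fell. Of 15 immediate early genes 3 fell and none rose (6 when adjusted over the list alone). Of the glucocorticoid targets 8 of 17 fell and 2 rose, over all genes and over the list alone, and Il1rl1 was at 467 in 4h MDI and 6.16 in 24h MDI. Of the cAMP targets 6 of 17 fell and none rose (8 when adjusted over the list alone). Each of 20 mitotic genes rose, as did 20 of 25 DNA replication genes, with 1 that fell (22 and 1 over the list alone). Of 26 matrix genes 14 fell and none rose (18 fell and 1 rose over the list alone), and 9 of 18 interferon-stimulated genes fell (13 over the list alone). Cholesterol synthesis genes had 6 of 19 up and 1 down, Pmvk (8 and 1 over the list alone). The counts over all genes were 1105 up and 1021 down, or 2126 in total. Without the filter on low values 343 passed, and at a threshold of 0.1 4413 did.

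Inflammatory and NF-kB targets and stress genes changed with time in both directions. Of 17 inflammatory genes 4 rose and 1 fell at 4h (5 and 2 when adjusted over the list alone), and 1 rose and 6 fell between 4h and 24h (1 and 9 over the list alone). Of 16 integrated stress and ER stress genes 2 rose and 1 fell at 4h (5 and 3 over the list alone), and 5 fell between 4h and 24h, over all genes and over the list alone. Secreted factors had 1 rise and 4 falls among 26 at 24h against 0h, over all genes and over the list alone. Of the brown and beige fat genes 3 were measured, and 1 fell at 4h and at 24h against 0h. Markers of other cell types were mostly unmeasured: in the Pro pair Tnnt2, a muscle troponin gene, was at 20.2 in MDI and 85.1 in CM, and the bone regulator Runx2 at 4.56 and 11.4, and no endothelial marker was measured in any pair. At 4h the muscle and bone markers measured were lower in CM, with Tnnt2 at 4.04 in MDI and 1.41 in CM, Runx2 at 7.51 and 2.95, and Alpl at 2.62 and 0.758.

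The second question was how conditioned medium differed from fresh MDI at the same time. At 4h, contractile and mechanically responsive genes were lower in CM. Of 12 measured actin and SRF or YAP target genes 11 were at least 2-fold lower, with a median of -1.76, below all 10000 random lists. Ctgf (chromosome 10, 24595442 to 24598682), a matricellular growth factor, was at 16.5 in MDI and 0.118 in CM, and Cyr61 at 423 and 77.6. Immediate early genes were also lower in CM, with a median of -0.77 and 6 of 14 at least 2-fold lower, Ier3 among them (147 and 50.5). Of the secreted factors 8 of 24 were at least 2-fold lower and 2 higher, including the growth factor genes Fgf2 (33.9 and 3.44) and Ereg (38.9 and 4.33), and Timp1, a metalloproteinase inhibitor of the matrix list, was at 941 and 128. Pparg (chromosome 6, 115361221 to 115490401), the central regulator of fat cell formation, was higher in CM, at 13.1 in MDI and 43.5 in CM. The medians of the early adipogenic regulators and the mature adipocyte genes were 0.43 and 0.47 higher, at percentiles 100 and 99.96 of the random lists, with 1 of 17 early regulators at least 2-fold higher and 1 lower, and 2 of 10 mature adipocyte genes higher and none lower. Glucocorticoid and cAMP targets had medians of -0.13 and -0.07, both inside the random range. Of the glucocorticoid targets 2 of 17 were at least 2-fold higher in CM and 3 lower, and of the cAMP targets 4 of 15 were lower and none higher, among them Nr4a3 (14.9 in MDI and 3.16 in CM). In total 119 genes were at least 2-fold higher and 319 lower in CM, or 181 and 309 after rescaling to TPM. The authors' deposited table held no gene at q under 0.1 for this pair. With a pseudocount of 0.1 the count was 660, and with 5 it was 241.

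At 24h, fat cell genes were higher in CM. Of 14 measured mature adipocyte genes 8 were at least 2-fold higher and none lower, with a median of 1.16, above all random lists. Some of the 14 had an FPKM under 1 in 24h MDI and were measured through 24h CM alone. Lpl (chromosome 8, 68880555 to 68906932), which releases fatty acids from circulating lipoproteins, was at 45.7 in MDI and 339 in CM, Fabp4, a fatty acid carrier, at 30.4 and 108, and the hormone-sensitive lipase gene Lipe at 21.6 and 61.8. Cebpa, which acts with Pparg, was at 16.0 in MDI and 38.3 in CM, Pparg itself at 32.7 and 54.1, and the early regulators had a median of 0.44. Dlk1 was at 551 in MDI and 307 in CM. Id2, an inhibitor of basic helix-loop-helix factors, was lower in CM (51.1 and 5.61), and Lrig1 (15.9 and 112), Gchfr (11.4 and 117) and Ephx2 (3.98 and 29.9) were higher.

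The medians of several metabolic and proliferative lists were lower in CM at 24h, with few members at least 2-fold different. Hypoxia and glycolysis genes had a median of -0.75, with 5 of 16 at least 2-fold lower, for example Bnip3 (log2 difference -1.12). Ldha, at 1122.5 in MDI and 569 in CM, was just under 2-fold lower. Cholesterol synthesis genes had a median of -0.71, with 1 of 19 at least 2-fold lower. Mitotic genes had a median of -0.61 with 1 of 20 at least 2-fold lower, Ccnb2 (96.9 and 44.8), and DNA replication genes a median of -0.23 with 0 of 25 at least 2-fold different. The percentiles among random lists were 0 for the first 3 of these lists and 0.04 for DNA replication. In total 211 genes were at least 2-fold higher and 164 lower, and none had q under 0.1 in the authors' deposited table. After rescaling to TPM, which shifted the ratios before the pseudocount by 0.12 on the log2 scale, the counts were 320 and 155. With a pseudocount of 5 the count was 176.

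**Figure D2:**
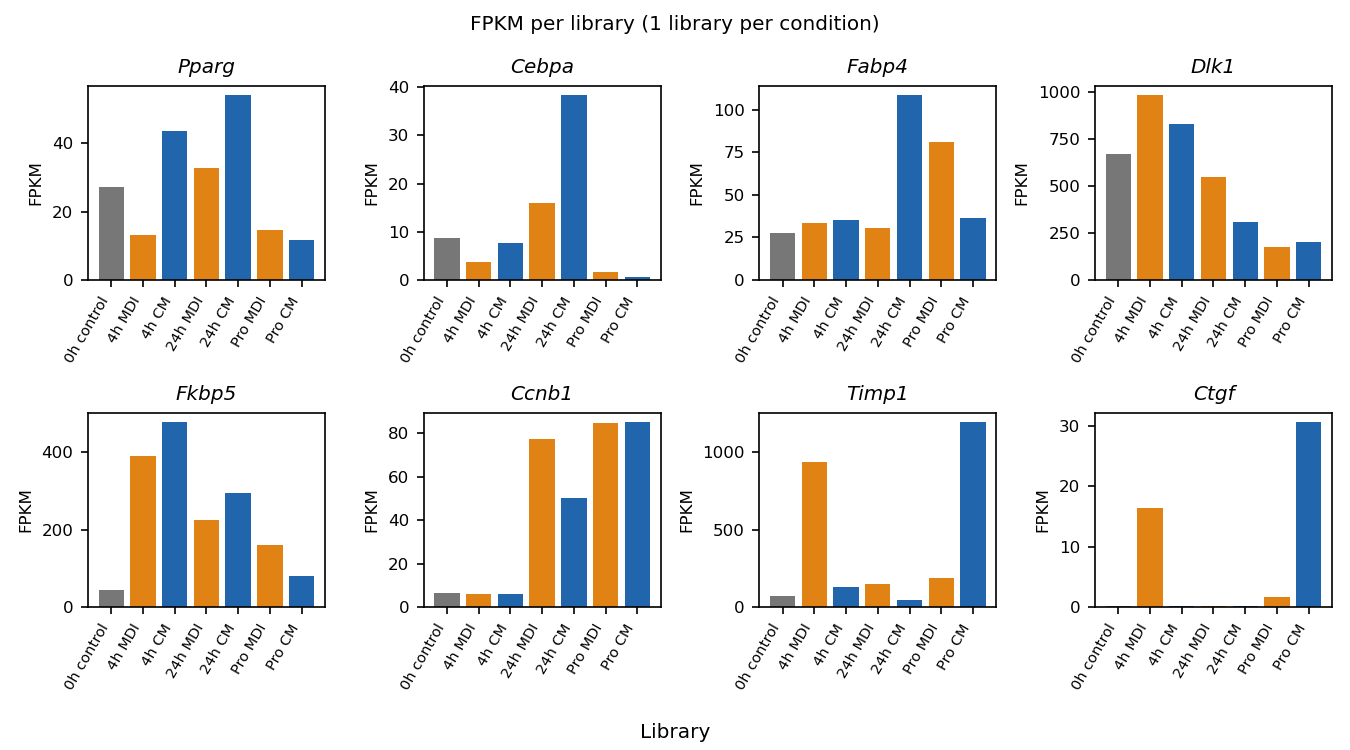
FPKM of 8 genes (y axis, linear from 0) in each of the 7 libraries (x axis), with the 0h control in grey, MDI in orange and CM in blue, 1 bar per library and no error bars because no condition was replicated. Fabp4 reached 108 in 24h CM against 30.4 in 24h MDI, whereas Timp1 was high in 4h MDI (941) and Pro CM (1194).

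In preconfluent cells the direction of several groups was the opposite of that at 4h. Ctgf was at 1.61 in the library labelled Pro MDI and 30.6 in the library labelled Pro CM, Timp1 at 186 and 1194, and Inhba, a subunit of activin, at 10.4 and 78.4. Pmepa1 (chromosome 2, 173224465 to 173276533), a feedback inhibitor of TGF-beta signalling, was at 6.23 and 117. Among genes at least 2-fold different with an FPKM above 0 in both libraries, only Pmepa1 had q under 0.1 for this pair in the authors' deposited table (q = 0.0338). Of the secreted factors 9 of 22 were at least 2-fold higher in CM and none lower, and of 12 actin and SRF or YAP targets 4 were higher and none lower. Mature adipocyte genes had a median of -0.53, with 3 of 10 at least 2-fold lower, and Fabp4 was at 81.2 in MDI and 36.7 in CM. The early regulators had a median of -0.31, and fatty acid synthesis genes one of -0.31 as well. Pdk4, which limits glucose oxidation, was at 21.4 and 3.38. Mitotic and DNA replication genes were level, with no member 2-fold different. In total 240 genes were at least 2-fold higher and 132 lower, and 191 in all with a pseudocount of 5.

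Across protein-coding genes with an FPKM of at least 5 in a treated library, the CM minus MDI differences at 4h and in the Pro pair, which share no library, were inversely related (Pearson r = -0.69, Spearman rho = -0.67 across 8895 genes, which are not independent replicates). Of 137 such genes 2-fold different in both pairs 135 went opposite ways, 113 of them lower in CM at 4h and higher in CM in the Pro pair. The same measure gave r = 0.09 for 4h against 24h and 0.01 for 24h against Pro, the other 2 relations of this family. Over all 11463 genes with an FPKM of at least 1 in a treated library, 4h against Pro gave r = -0.37 and rho = -0.62. Of 165 of these genes 2-fold different in both pairs, 154 went opposite ways.

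**Figure D3:**
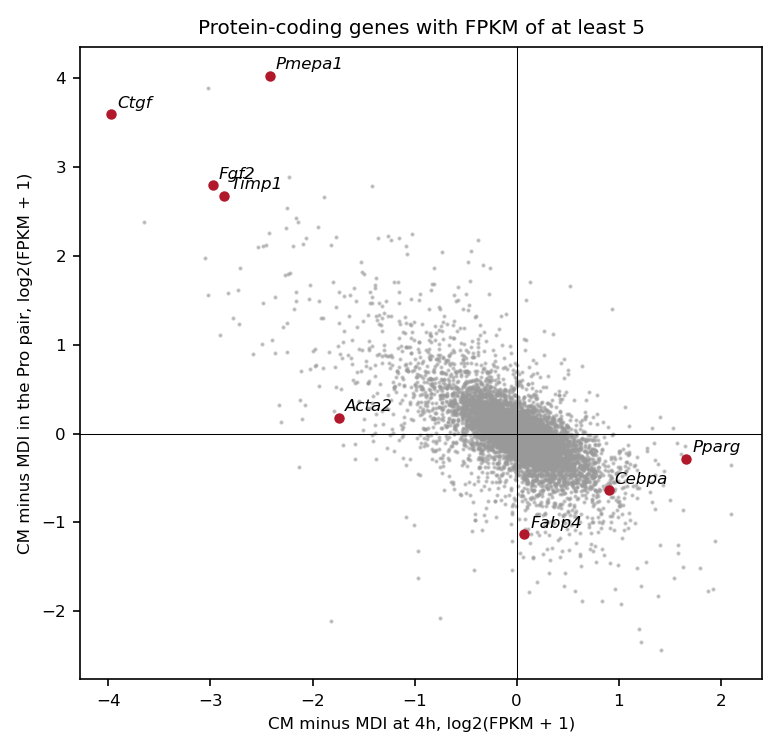
Each grey point is a protein-coding gene with an FPKM of at least 5 in a treated library, with its CM minus MDI difference at 4h on the x axis and in the Pro pair on the y axis, both in log2(FPKM + 1), and red points mark named genes. The cloud of 8895 genes slopes downwards (Spearman rho = -0.67), with Ctgf and Pmepa1 at the upper left.

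A medium effect shared by the 3 stages was tested in limma on the 6 treated libraries with stage as a block. No gene passed among 11463 at an adjusted p under 0.05, and 143 had an unadjusted p under 0.05. That is a smaller share of the genes than the 0.05 to be met if no gene differed. Among protein-coding genes that differed the same way at each stage, the smallest unadjusted p was that of Ndufs5, a subunit of respiratory complex I, but it was listed at 0 in each CM library, which can be a failed estimate, and no difference is given for it. It was followed by the actin-binding Cotl1 (log2 difference 0.76, SE 0.12, unadjusted p = 0.00169) and by Lxn (-0.71, SE 0.12, unadjusted p = 0.00275), and the adjusted p of these genes was 1. No member of any list passed, over all genes or when adjusted over the list alone. Camera with the preset correlation put cholesterol synthesis genes (adjusted p = 2.51e-10), interferon-stimulated genes (adjusted p = 5.83e-08), mitotic genes (adjusted p = 6.56e-06), inflammatory and NF-kB targets (adjusted p = 0.000202) and actin and SRF or YAP targets (adjusted p = 0.000369) lower in CM. Mature adipocyte genes were the only list it called higher in CM (adjusted p = 0.00188), and further lists called lower had adjusted p from 0.00729 to 0.0433. Not all of these calls were shared by the stages. At 4h, 24h and Pro the list medians were 0.47, 1.16 and -0.53 for mature adipocyte genes. They were -1.76, -0.33 and 0.33 for actin and SRF or YAP targets, and 0.04, -0.61 and -0.05 for mitotic genes. Cholesterol synthesis, interferon and inflammatory lists had medians below 0 at each stage, but not all lay outside the random range. Inside it were the inflammatory list at each stage (-0.13, -0.17 and -0.08), the interferon list at 24h (-0.12) and the cholesterol list in Pro (-0.13). Each list that camera called with the preset correlation had adjusted p = 0.555 with an estimated correlation. With 2 residual degrees of freedom that version could hardly call any list, so it does not decide these calls. Without the 24h pair 4 genes passed, and without either of the other pairs none did.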

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

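Except for the correction for gene length, GC content and expression, the tests in this part were chosen only after the result was seen. The difference between CM and MDI went opposite ways at different stages in 7 gene lists. Each median lay outside the middle 95 percent of random lists at both stages, but random lists lack the shared variation of list members. None of these differences between stages was tested. From 4h to the Pro pair, the list median of CM minus MDI moved by -0.74 for early adipogenic regulators (0.43 at 4h, -0.31 in Pro), by -1.0 for mature adipocyte genes (0.47 and -0.53), by 1.12 for immediate early genes (-0.77 and 0.35), by 2.09 for actin and SRF or YAP targets (-1.76 and 0.33), by 0.78 for secreted factors (-0.28 and 0.50) and by 0.47 for integrated stress and ER stress genes (-0.29 and 0.18). From 24h to Pro it moved by -0.75 for early regulators, -1.69 for mature adipocyte genes, 0.66 for actin and SRF or YAP targets and 0.90 for hypoxia and glycolysis genes. The measured members can differ between pairs, as for mature adipocyte genes, with 14 at 24h and 10 in Pro. From 4h to 24h secreted factors moved by 0.63.

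The medium differences at 4h and in the Pro pair were opposite across genes, with Ctgf and Pmepa1 lower in CM at 4h and higher in CM in the Pro pair. Weak expression argues poorly for it, since rho was -0.70 over 4021 protein-coding genes with a mean FPKM of at least 20, and after correction for length, GC content and expression rho was -0.66 over 8530 genes (-0.67 before). Exchanged media labels within a pair cannot be told apart from a true difference between stages: of 4 lists that could be compared, 3 had at 24h the sign of the 4h pair and 1 that of the Pro pair. The bound set against an exchange, at least 1 in 4 of the lists with each sign, was met, but by 1 list alone. It is left undecided because 4 lists are too few, under a minimum of 8 that was chosen only after their number was known, and because 24h cells need not resemble either pair. A response to CM that depends on confluence or time may also be the source, and was not tested.

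Interferon-stimulated genes such as Isg15 and Oasl2 were higher in the 0h library than in the treated libraries. Leukocytes in that culture are unlikely, since the highest FPKM of Ptprc, Lyz2 and Tyrobp at 0h was 0.34. Scaling of the 0h library argues poorly for it too, since after rescaling the list median nearest to 0 was -1.22. The 0h state is a single library, so treatment, time and culture state remain open and were not tested.

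Small RNA genes gave 14 to 20 of the 20 largest differences in each comparison. Few reads on very short transcripts may be the source: in the medium pairs 35% of small RNA genes with an FPKM of at least 5 in a library (82 of 234) were listed at 0 in the other, against 0.01% of protein-coding genes (2 of 24329). No biological explanation was tested.

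For the medium effect shared by the 3 stages, limma called 0 genes (143 at an unadjusted p under 0.05). With a real count of 0, each of the 10 splits of the 6 treated libraries gives as many whatever the data, and the splits are too few for a share under 0.05. The highest other count, 15, came from splits that put both libraries of a stage on the same side, while the splits that divide each stage, as the real one does, gave 1 with the Pro pair reversed, 0 with the 4h pair reversed and 2 with the 24h pair reversed. At an unadjusted p under 0.05 these splits gave 1064, 1517 and 81 genes. The first 2 counts are several times the real one and point to the opposite medium differences of the 4h and Pro pairs; they are high whichever of these pairs is reversed, so they do not show which, if either, has exchanged labels.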

How the results depend on the processing

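The fit without the 4h libraries and the counts of protein-coding genes alone were tests chosen only after the result was seen. Among list medians outside the middle 95 percent of random lists, none changed sign with another pseudocount, without the filter or after rescaling to a median ratio of 1, and no named gene did with another pseudocount or after that rescaling. The balance of directions in counts did turn: 4h CM against 0h had 1075 higher and 1054 lower, but 739 and 2048 after rescaling to TPM, and 4h MDI had 1531 and 1599, but 1069 and 582 with a pseudocount of 5. The balance of 24h MDI against 0h and of the 3 time contrasts also turned under at least 1 alternative. Of the counts under alternatives 69 stayed within 1.5 times the reported count and 16 moved. Of list medians 260 stayed and 48 moved, and of the values of the checked named genes 306 stayed and 33 moved. With a pseudocount of 5 the pair counts were 1651 (4h MDI against 0h), 1204 (24h MDI), 1071 (4h CM), 1033 (24h CM), 241 (CM against MDI at 4h), 176 (24h) and 191 (Pro), as a larger pseudocount shrinks differences of weakly expressed genes. With a pseudocount of 0.1 CM against MDI at 4h gave 660. Without the filter on low values limma gave 1185 genes for 4h against 0h and 343 for 24h against 4h; the cause was not tested. At a Benjamini-Hochberg threshold of 0.1 the time contrasts gave 4051 (4h against 0h), 2695 (24h against 0h) and 4413 (24h against 4h), by construction more. Without the 4h libraries 24h against 0h gave 793, with fewer libraries. The shared medium effect ranged from 0 to 4 when a pair was left out, with 4 without the 24h pair, and the rule of at least 2-fold the same way at the 3 stages, with no test, took 2 genes, Mir719, a small RNA gene, and Ndufs5, which was listed at 0 in each CM library and can be a failed estimate there; the cause was not tested. Protein-coding genes alone gave 2926, 2116, 1966, 1925, 378, 319 and 316 in the order of the pairs above. The fit of the medium effect paired CM with MDI by stage, and pairing by replicate number does not apply, since each condition has 1 library. Depth is unknown, so its limit on weakly expressed genes was not measured.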

Other observations

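The test in this part was chosen before its result was seen. A hypothesis was that conditioned medium moves cells at 4h further along the course to 24h, since Pparg was higher in CM at 4h. Across 9220 protein-coding genes, which are not independent replicates, the CM minus MDI difference at 4h and the difference between the 24h mean and 0h had rho = -0.05, against at least 0.2 under that hypothesis, and the Pro pair gave 0.01. The value is below the bound set against that hypothesis, an advanced program in conditioned medium, for a shift across all these genes. It cannot decide on an advance of some lists only, since they hold few of these genes. Nor can it decide for genes that peaked at 4h, since the difference from 0h does not hold their path from 4h to 24h. Median differences of mature adipocyte genes (CM minus MDI at 4h 0.47, 24h against 0h 1.13) and early regulators (0.43 and 0.56) had the same sign. So did those of actin (-1.76 and -1.07) and interferon lists (-0.52 and -2.6). Immediate early (-0.77 and 0.26) and cholesterol synthesis lists (-0.17 and 0.28), among others, went opposite ways. For 24h against 4h the median of immediate early genes was -0.84, which has the sign of their CM minus MDI difference at 4h. That of cholesterol synthesis genes was 0.69, still the opposite sign.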
